A study of Homo sapiens with 9 samples.

How the data were processed

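Total RNA of HuCCT1 cells was hybridised to single-colour arrays with a biotin label, per the labels. The deposited values are log2 signals per probe set for 9 arrays and 54675 probe sets, as judged from its range of about 1.6 to 15, since no header states the unit. The method of normalization, summarisation and background correction is not given in the sources used here. The deposited log2 values appear to have been normalized between arrays, because the medians of the arrays lie between 5.95 and 5.97. No further scaling was applied for the main results. There were 0 columns of other samples.

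Groups were taken from the vector named in the labels, 4 arrays with the empty vector and 5 with YAP S127A. After 62 control probe sets were set aside, 54613 were tested. A platform annotation named 1 gene for 41091 of them, several for 1801 and none for 11721. Symbols were updated through the gene ID in the RefSeq table of GRCh38.p14, which matched 41037 probe sets. Each of 19775 genes was represented by its brightest probe set over all arrays. Of the called genes, 3580 have several probe sets, and 76 of these have a probe set called in the opposite direction.

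The groups were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes and no covariate. P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05, and the fits had 11.4 total degrees of freedom. Errors printed with a log2 difference are standard errors (SE) and those printed with a level are SDs. The 26 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside an estimated correlation and fry. Only members with a named probe set were counted. Single measures of arrays and chromosomes were compared by exact permutation of the group labels, 2-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

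The rule for named genes was also fixed before the data were examined. It takes YAP1, CCN1, CCN2, ANKRD1, AXL and MFAP5 in any case. It adds the 10 highest and 10 lowest log2 differences among genes that passed, did not overlap between groups and had a mean in the higher group above 5.96, the median of all probe sets. For each list it adds the members with the lowest p-values, up to 4. Chosen after their values were seen were CCNE2, PLK1, JAG2, INHBA, BMP4, SESN3, NDRG1, EGLN3, EGR1 and FOS, to complete counts of at most 2 in a list, and the genes of later tests (COL1A2, COL3A1, DCN, AKR1B10, AKR1C1, AKR1C2, AKR1C3, KLK5, KLK6 and KLK10), as well as KRT7, KRT19 and POSTN.

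Shifts shared by neighbouring genes were noticed in the data and then measured. For each gene the median difference of up to 50 neighbours was taken on each array, and in an added alternative it was subtracted before the fit. The subtraction assumes that the signal of a gene follows its neighbours. Where it does not, the subtraction can create a difference in a gene that hardly moved. Chromosomes were described for 12189 genes with a signal above the median. No base positions are given, since no genome build is named for the array.

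The scripts were tested on simulated data for the same comparison, with 50 probe sets changed at each size among 54613. The share recovered was 4% at a log2 difference of 0.25, 52% at 0.5, 100% at 1 and 100% at 2, with 3 false calls. The simulated noise was independent between probe sets. With so few probe sets changed, the adjusted threshold is stricter than in the real data, where 13052 passed. The shares therefore do not carry over to the real arrays. The planted gene list was recovered and 0 unchanged lists were called. On the real arrays, however, 48 of 99 other splits into 4 and 5 called at least 1 list with camera at the preset correlation. Of the 50 splits with 2 empty vector arrays in the group of 4, the most even mixture, 3 did so. The less even ones keep part of the group difference. The breakdown by mixture was chosen after seeing the counts. In the simulation, small differences were called only in part.

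The alternatives were quantile normalization, centring of each array on its median, leaving out dim probe sets, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, the mean over a gene's probe sets, an estimated inter-gene correlation and fry. Chosen after seeing the data were the actin 3' to 5' gap as a covariate, leaving out both arrays with the largest gap, and the neighbours' median removed. A pseudocount planned for linear values was not needed, because the values are on a log scale.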

Results

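Transcript levels were measured on 9 single-colour microarrays in HuCCT1, an established human cell line from a cholangiocarcinoma, a cancer of the bile ducts. Of these arrays, 4 carried RNA of cells given an empty vector and 5 carried RNA of cells given YAP S127A. This mutant of the transcriptional co-activator YAP1 is constitutively active, because it lacks a serine that LATS kinases of the Hippo pathway phosphorylate to keep the protein out of the nucleus. The comparison asks which transcripts differ when the active form is overexpressed. The labels number the samples within each group but do not say that they came from separate cultures or transfections. The p-values therefore measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. The median log2 signal per array lay between 5.95 and 5.97.

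Cells with YAP S127A differed from empty vector cells across much of the transcriptome, with about as many genes higher as lower. The highest rise was that of NPPB, which encodes natriuretic peptide B, from a log2 signal of 6.39 ± 0.12 (SD, n = 4) to 11.80 ± 0.17 (SD, n = 5), or 42.5-fold. The intermediate filament gene VIM rose from 8.26 ± 0.15 (SD, n = 4) to 12.40 ± 0.09 (SD, n = 5), or 17.6-fold. The deepest fall was that of CDH6, a cadherin of cell-cell adhesion, from 11.22 ± 0.17 (SD, n = 4) to 6.56 ± 0.12 (SD, n = 5), or 25.2-fold lower. With limma and Benjamini-Hochberg adjustment, 5676 of 19775 genes (28.7%) changed, 2874 higher and 2802 lower. Of these, 619 changed at least 2-fold, 318 higher and 301 lower. Among all 54613 probe sets tested, 13052 changed (6506 higher, 6546 lower). The first principal component held 73.9% of the variance. The SD of the differences between 2 arrays was 0.14 to 0.27 within groups (16 pairs) and 0.46 to 0.51 between groups (20 pairs).

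After NPPB (+5.41 on the log2 scale, SE 0.09, adjusted p = 3.28e-11), the highest differences were those of C16orf54 (+4.18), the long non-coding transcript SFTA1P (+4.15), VIM (+4.13, SE 0.08, adjusted p = 9.02e-11) and the cell adhesion gene CADM1 (+3.91). The interleukin 7 receptor gene IL7R rose by 3.80, STXBP6, whose product binds proteins of vesicle fusion, by 3.73, FAM133A by 3.59, and GPC6, a glypican of the cell surface, by 3.39. MFAP5, a glycoprotein of extracellular microfibrils that was named in advance, rose by 3.36 (SE 0.07, adjusted p = 1.49e-10), with all 3 of its probe sets higher. Averaged over their probe sets, VIM, CADM1 and GPC6 were higher by 2.36, 1.11 and 2.07. With the empty vector, C16orf54, CADM1, FAM133A and GPC6 had mean levels of 4.20, 3.71, 4.10 and 4.15. These lie below the lower quartiles of the arrays (4.24 to 4.27), so the size of these rises depends on the background.

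The 10 lowest differences were led by CDH6 (-4.65, SE 0.09, adjusted p = 9.02e-11), for which all 6 probe sets fell. They went on with LRRN1 (-4.23), DOCK10 (-4.18), GPR137B (-4.06) and MTSS1 (-3.83), which binds actin and membranes. Falls followed for PLA2G4A (-3.79), the cytosolic phospholipase that releases arachidonic acid, and the protease inhibitor gene SPINK4 (-3.63). The ubiquitin ligase gene RNF128 (-3.53), the matrix gene MXRA5 (-3.42) and DACT1 (-3.42), a regulator of Wnt signalling, completed the set. Averaged over their probe sets, DOCK10 and MTSS1 were lower, at -2.12 and -1.25. With YAP S127A, PLA2G4A and MXRA5 had mean levels of 2.57 and 3.86, also below the lower quartiles of the arrays, so the size of their falls depends on the background. In these 20 genes every array of one group lay above every array of the other, and no probe set of the same gene was called in the opposite direction.

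**Figure D1:**
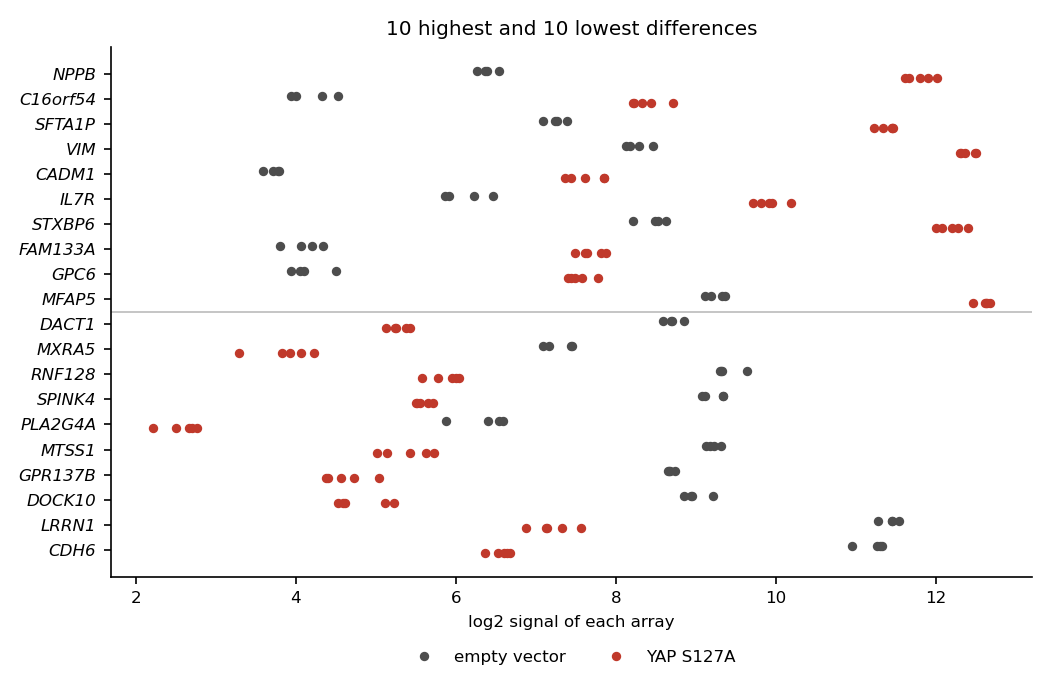
Log2 signal (horizontal axis) of each array for the 10 genes with the highest and the 10 with the lowest difference, at the brightest probe set of each gene. Grey points are the 4 empty vector arrays and red points the 5 YAP S127A arrays; NPPB lies near 6.39 in the former and 11.80 in the latter, and the groups do not overlap for any gene shown.

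Genes on several chromosomes moved together. Among 12189 genes with a signal above the median and a known position, chromosome 16 had 348 genes higher and 9 lower of 571, with a median log2 difference of +0.34. Chromosome 13 had 138 higher and 10 lower of 209 (median +0.35), and chromosome 10 had 264 higher and 24 lower of 473 (median +0.28). Chromosome 22 had 115 higher and 11 lower of 297 (median +0.16). In the other direction, chromosome 8 had 45 higher and 174 lower of 433 (median -0.18), and chromosome 17 had 57 higher and 231 lower of 728 (median -0.11). The 4 chromosomes with medians above 0.1, namely 10, 13, 16 and 22, held 12.7% of these genes and 33.8% of the genes that rose. Per array, the chromosome 16 median was 0.336 ± 0.041 (SD, n = 5) in YAP S127A cells and 0.002 ± 0.018 (SD, n = 4) in empty vector cells, relative to the empty vector mean (2-sided exact permutation test, p = 0.00794, adjusted p = 0.0152 over 23 chromosomes). The SD of the chromosome medians was 0.137, against at most 0.0274 in 10000 random permutations of gene positions (p = 1e-04, the smallest they can give). Chromosome and gene order were taken from the RefSeq annotation of GRCh38.p14, used only for which genes neighbour each other.

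**Figure D2:**
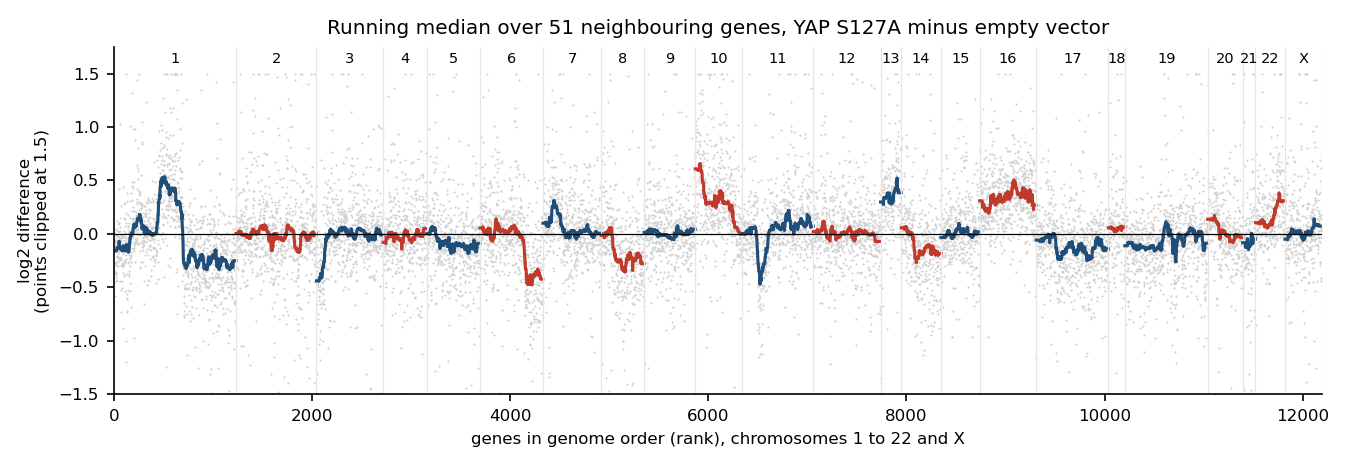
Log2 difference between YAP S127A and empty vector cells (vertical axis) for 12189 genes in genome order (horizontal axis, rank), with grey points for single genes, clipped at 1.5, and lines for the running median over 51 genes, alternating in colour by chromosome. The line stays above 0 over most of chromosomes 10, 13 and 16, whose medians are +0.28, +0.35 and +0.34, and below 0 over much of chromosome 8 (median -0.18).

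YAP1 itself was not called higher. Its brightest probe set had a log2 signal of 12.56 ± 0.06 (SD, n = 4) with the empty vector and 12.71 ± 0.07 (SD, n = 5) with YAP S127A. The difference of +0.15 (SE 0.06) had an adjusted p = 0.121 in limma and p = 0.0159 in a 2-sided exact permutation test. The other 2 probe sets differed by +0.16 (adjusted p = 0.171; exact permutation p = 0.0714) and +0.03 (adjusted p = 0.803; exact permutation p = 0.492). The positions of these probe sets in the transcript are not given in the sources used here. A construct of coding sequence alone would not be read by probe sets in untranslated regions. Whether these probe sets can read the construct is unknown, so their values do not check the labels.

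Of known YAP/TAZ target genes more rose than fell. Of 21 members with a named probe set, 11 rose, 2 fell and 8 did not pass; adjusted over the list alone, 14 rose and 2 fell. ANKRD1, an ankyrin repeat gene and a standard readout of YAP activity, rose by 2.24 (SE 0.13, adjusted p = 3.38e-07), or 4.73-fold. IGFBP3, which encodes a binding protein of insulin-like growth factors, rose by 0.75, and LATS2, which encodes a kinase that inhibits YAP, rose by 0.69. The matricellular gene CCN1 rose by 0.45 (SE 0.08, adjusted p = 0.00114), while CCN2 differed by +0.22 (SE 0.09, adjusted p = 0.107). FJX1 (-0.68) and the receptor tyrosine kinase gene AXL (-0.30) fell, AXL with an SE of 0.06 (adjusted p = 0.00172) and at 1 of its 2 probe sets. The list had a median of +0.39 and camera gave an adjusted p = 0.0056, with an adjusted p = 0.0708 with an estimated correlation. Neighbouring genes of CCN1 also lay higher, by a median of 0.45, and those of CCN2 lower (-0.51). Once the neighbours' median was removed on each array, CCN1 differed by -1.79e-05 (adjusted p = 1.00), CCN2 was higher by 0.73 (adjusted p = 0.000213), ANKRD1 was higher by 1.85, and the list kept its call (adjusted p = 0.0229). For CCN1 this value covers only the brightest probe set. Its other probe set rose by 0.66 (SE 0.06, adjusted p = 9.42e-06), more than the neighbours, so they need not account for the whole rise of CCN1. LATS2 was then higher by 0.43, and FJX1, whose neighbours lay lower (-0.42), was at -0.27 (adjusted p = 0.0409).

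**Figure D3:**
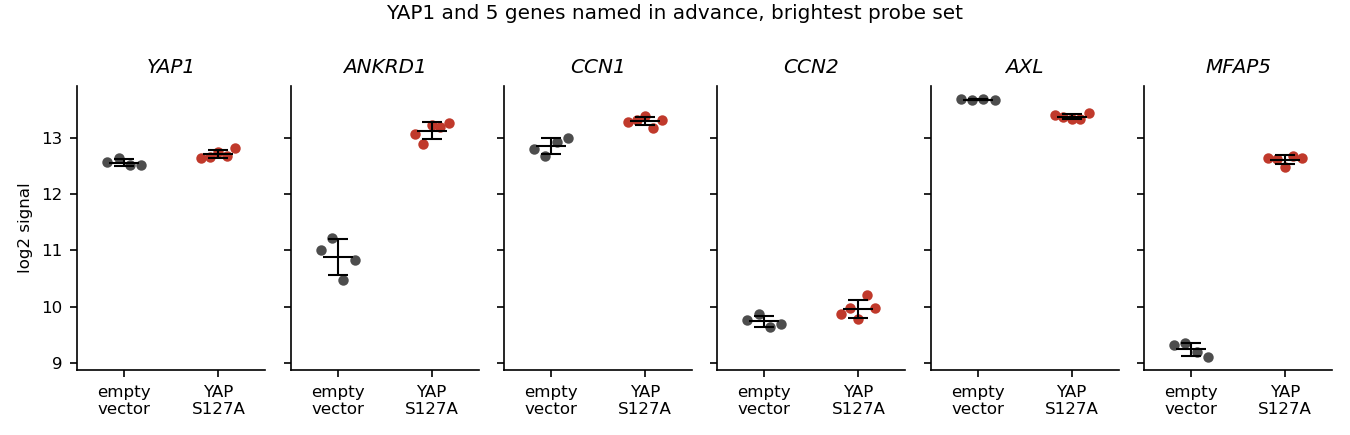
Log2 signal (vertical axis) of each array for YAP1 and 5 genes named in advance, at the brightest probe set, with points for arrays and black bars for the mean and SD of the 4 empty vector and 5 YAP S127A arrays. YAP1 differs by +0.15, ANKRD1 by +2.24, CCN1 by +0.45, CCN2 by +0.22, AXL by -0.30 and MFAP5 by +3.36.

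Inflammatory genes driven by NF-kB fell. Of 16 members with a named probe set, 13 fell, 1 rose and 2 did not pass; adjusted over the list alone, 15 fell and 1 rose. The neutrophil chemokine genes CXCL6 (-2.55) and CXCL2 (-1.86) fell, as did the cytokine gene IL6 (-1.92, SE 0.08, adjusted p = 2.29e-08). The exception was CCL2, a chemokine for monocytes, which rose by 2.54 (SE 0.10, adjusted p = 1.55e-08). CXCL2 was at -1.23 as the mean of its probe sets. CXCL8, counted among the angiogenic factors, also fell (-1.52). The median was -0.65 and camera gave an adjusted p = 7.33e-09, and the call held with an estimated correlation (adjusted p = 0.00678) and with the neighbours' median removed (adjusted p = 1.36e-06).

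Cholesterol synthesis genes rose. Of 11 members with a named probe set, 8 rose, none fell and 3 did not pass; adjusted over the list alone, 9 rose. IDI1, which isomerises isopentenyl diphosphate, rose by 0.90, HMGCS1, which makes the precursor of mevalonate, by 0.61, SREBF2, the transcription factor of the pathway, by 0.68, and the decarboxylase gene MVD by 0.66. The median was +0.33 and camera gave an adjusted p = 7.92e-05 (adjusted p = 0.0272 with an estimated correlation). IDI1, SREBF2 and MVD lie on chromosomes 10, 22 and 16, and their neighbours lay higher by 0.60, 0.35 and 0.27. After removal of the neighbours' median, 9 members were higher, with IDI1, SREBF2 and MVD at 0.31, 0.33 and 0.39, and the list had an adjusted p = 0.000179.

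Some markers of cholangiocytes, the epithelial cells of bile ducts, fell, and more did not pass. Of 21 members with a named probe set, 9 fell, none rose and 12 did not pass, and the counts were the same adjusted over the list alone. The chloride channel gene CFTR (-2.72), the trefoil factor gene TFF1 (-1.46), the secreted phosphoprotein gene SPP1 (-1.37) and the mucin gene MUC1 (-1.06) fell most clearly, by p-value. CFTR was at -0.97 as the mean of its probe sets. The keratin genes KRT19 (+0.02, adjusted p = 0.886) and KRT7 (-0.11, adjusted p = 0.203), standard markers of these cells, did not pass, although KRT7 did with trend and robust eBayes (adjusted p = 0.0340). The median was -0.17 and camera gave an adjusted p = 0.00141, and the call was lost with an estimated correlation (adjusted p = 0.106). The adjusted p was 0.00342 with the neighbours' median removed.

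Genes of the TGF-beta and BMP response fell more often than they rose. Of 19 members, 8 fell, 2 rose and 9 did not pass, and the counts were the same adjusted over the list alone. LTBP1, which encodes a protein that holds latent TGF-beta in the matrix, fell (-2.76), as did the ligand gene BMP2 (-1.85) and the BMP target genes ID1 (-1.07) and ID3 (-0.98). As the mean of its probe sets LTBP1 was at -1.62. The ligand genes BMP4 and INHBA rose by 0.81 and 0.34. The neighbours of INHBA lay higher by 0.19, and with their median removed its difference was +0.16 and did not pass. The median of the list was -0.21 and camera gave an adjusted p = 0.029, with an adjusted p = 0.106 with an estimated correlation. The call was lost when dim probe sets were left out (adjusted p = 0.0839), and with the neighbours' median removed the adjusted p was 0.0366.

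The other 21 lists were not called by camera, although most held members that changed. Among mesenchymal genes (adjusted p = 0.378), 7 of 19 rose and 3 fell: besides VIM, SPARC and LOX rose by 1.40 and 1.34, and the matrix gene TNC fell (-2.73). The neighbours of VIM, on chromosome 10, lay higher by 0.63. Among epithelial junction genes (adjusted p = 0.792), 4 of 22 rose and 5 fell, with ELF3 (-0.66) and JUP (-0.58) lower and PKP2 higher by 0.54. Among Hippo pathway components (adjusted p = 0.893), 5 of 23 rose and 7 fell, with VGLL1 higher by 1.01 and AMOT (-1.34) and LATS1 (-0.83) lower. The neighbours of LATS1 lay lower, at -0.35, and with their median removed it was at -0.47. Among matrix and integrin genes (adjusted p = 0.804), 4 of 17 rose and 4 fell, with COL12A1 higher by 1.44 and ITGB8 lower (-1.51). Among SRF and actin cytoskeleton genes (adjusted p = 0.271), 7 of 16 rose, among them ACTA2, TPM2 and FHL2 by 0.89, 0.82 and 0.67, and EGR1 (-0.54) and FOS (-0.50) fell. Averaged over probe sets, SPARC, ACTA2 and TPM2 were higher by 0.89, 0.33 and 0.51, and TNC and ITGB8 were at -0.90 and -0.86. ACTA2 was higher by 0.52 with the neighbours' median removed.

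Growth factor and signalling lists held members moving both ways. The EGF family list also holds other receptor kinases and GAS6, which belongs to neither class. Of its 15 members (adjusted p = 0.792), 7 rose and 4 fell, with BTC (-1.97), EGF (-1.92) and EREG (-0.87) lower and GAS6 higher by 0.81. Of 19 angiogenic factors (adjusted p = 0.539), 5 rose and 3 fell, with ADM and EDN1 higher by 0.72 and 0.65 beside MFAP5. Of 18 Notch pathway genes (adjusted p = 0.403), 5 fell, among them HEY1 (-1.08), LFNG (-0.59) and JAG1 (-0.43), and JAG2 rose by 0.32. Of 18 immediate-early genes (adjusted p = 0.378), 5 rose and 7 fell, with DUSP1 higher by 0.73 and IER3 lower (-0.53). The immediate-early list was called lower with the neighbours' median removed (adjusted p = 0.0366). Of 22 interferon-stimulated genes (adjusted p = 0.539), 5 rose and 8 fell. IFIT1, IFIT2 and IFIT3, which lie on chromosome 10 with neighbours higher by 0.37 to 0.39, rose by 1.85, 1.22 and 1.03, and ISG15 fell (-0.58). Removal of the neighbours' median left IFIT3 at 0.65, GAS6 at 0.45 and JAG2 at 0.53, and EREG was at -1.34 as the mean of its probe sets.

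Proliferation and stress lists were not called either. Of 23 DNA replication genes (adjusted p = 0.443), 6 rose, among them GINS2, ORC1 and TYMS by 0.52, 0.49 and 0.36, and MCM4 (-0.34) and CCNE2 (-0.50) fell. With the neighbours' median removed, GINS2, ORC1, MCM4 and CCNE2 no longer passed. Averaged over their probe sets, GINS2 and TYMS were higher by 0.29 and 0.21. Of 22 mitosis genes (adjusted p = 0.278), 5 fell, among them CENPF (-0.70), KIF20A (-0.58) and TOP2A (-0.36), and CDK1 and PLK1 rose by 0.29 and 0.32. The neighbours of CDK1 and PLK1 lay higher by 0.32 and 0.30. With that median removed neither passed, and they differed by -0.03 (adjusted p = 0.803) and +0.02 (adjusted p = 0.903), while CENPF and TOP2A were at -0.43 and -0.22. Of 16 p53 target genes (adjusted p = 0.278), 3 rose and 5 fell, with TP53INP1 (-1.40) and CDKN1A (-0.61) lower and FAS higher by 0.79. TP53INP1 was at -0.48 as the mean of its probe sets, and FAS at 0.43 with the neighbours' median removed. Of 16 apoptosis regulators (adjusted p = 0.378), 3 rose and 6 fell, with CFLAR (-0.90) and BMF (-0.69) lower. Of 16 hypoxia and glycolysis genes (adjusted p = 0.129), 7 rose, among them PFKFB3, P4HA1 and PDK1 by 0.98, 0.83 and 0.81, and NDRG1 (-0.50) and EGLN3 (-0.35) fell. PFKFB3 and P4HA1 lie on chromosome 10, with neighbours higher by 0.60 and 0.32. Without the neighbours' median PFKFB3, P4HA1 and NDRG1 were at 0.38, 0.51 and -0.30. Averaged over probe sets, P4HA1 and PDK1 were at 0.46 and 0.43, and EGLN3 was at -0.16 and no longer passed (adjusted p = 0.208). Of 16 genes of the unfolded protein and amino acid response (adjusted p = 0.293), 6 rose, among them ASNS and CHAC1 by 0.65 and 0.61, and SESN3 fell (-0.44). The call of SESN3 was lost without empty vector replicate 1 (-0.45), empty vector replicate 4 (-0.32) or YAP S127A replicate 4 (-0.36), and with the mean of its probe sets (-0.09, adjusted p = 0.266). ASNS was at 0.37 as such a mean. Of 20 drug transport and detoxification genes (adjusted p = 0.852), 6 rose and 5 fell. ABCC4, GCLM and ABCC1 rose by 0.61, 0.52 and 0.44, with neighbours higher by 0.45, 0.43 and 0.35, and none passed with the neighbours' median removed.

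Markers of other cell types and reference genes gave no called list. Of 15 hepatocyte markers (adjusted p = 0.792), CPS1, a urea cycle enzyme, rose by 2.09 and SERPINA1 fell (-0.62). TAT fell (-0.18), a call that was lost without any of 8 of the 9 arrays (adjusted p 0.0316 to 0.0921, kept only without YAP S127A replicate 2). It was also lost with the mean of its probe sets (-0.02, adjusted p = 0.854). With the neighbours' median of +0.36 subtracted TAT was at -0.54. Of 12 fibroblast markers (adjusted p = 0.792), LUM rose by 1.45 while MXRA5 (-3.42) and COL1A1 (-0.70) fell. Of 12 blood and endothelial markers (adjusted p = 0.403), LYZ (-2.25), CD14 (-0.45) and HBB (-0.24) fell. The call of HBB was lost without any of 8 of the 9 arrays (adjusted p 0.0283 to 0.136, kept only without empty vector replicate 2), and also with quantile normalization (adjusted p = 0.0601). Averaged over their probe sets, LUM, COL1A1 and LYZ were at 0.94, -0.40 and -1.19. Of 13 cytosolic ribosomal protein genes, none passed in limma (adjusted p = 0.701 for the list). RPL8 (-0.10) passed with trend and robust eBayes (adjusted p = 0.0321). RPL7 differed by -0.07 as measured. It was at +0.25 only after the median of its neighbours, -0.32, had been subtracted (adjusted p = 0.0074). The median, mean and camera direction differed in sign for the Hippo (+0.02, -0.02, up), epithelial junction (+0.03, -0.03, down), hepatocyte (-0.02, +0.08, down), EGF family (+0.03, -0.13, up) and fibroblast (+0.03, -0.19, down) lists. Adjusted over the list alone, the counts of higher and lower members became 6 and 7 (Hippo), 9 and 3 (mesenchymal), 5 and 5 (epithelial), 2 and 5 (Notch), 7 and 5 (EGF family), 4 and 6 (apoptosis), 6 and 2 (unfolded protein), 5 and 6 (matrix) and 6 and 9 (immediate-early), and did not change for the remaining 12 lists that were not called.

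**Figure D4:**
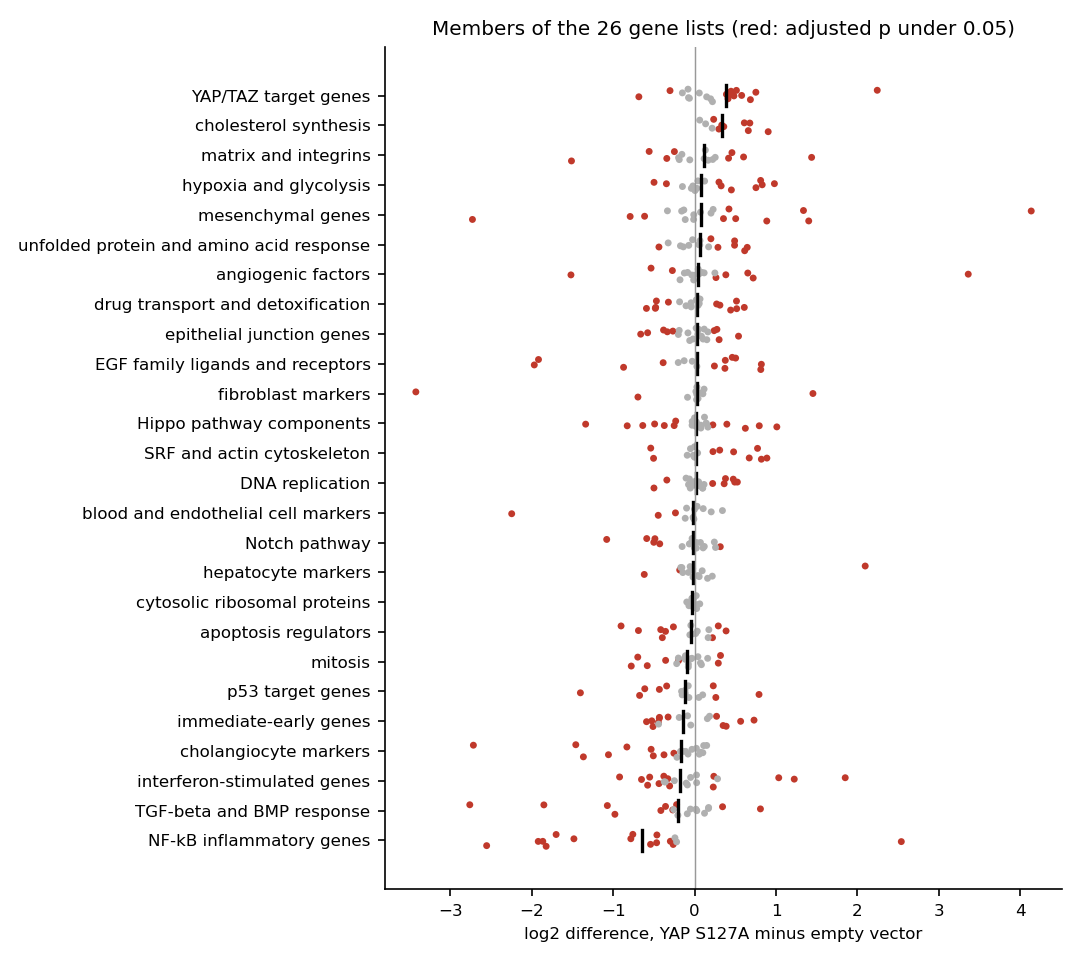
Log2 difference between YAP S127A and empty vector cells (horizontal axis) for each measured member of the 26 gene lists (rows), with red points for members that passed an adjusted p of 0.05, grey points for those that did not, and black bars for the list medians. The medians run from +0.39 for YAP/TAZ target genes to -0.65 for NF-kB inflammatory genes.

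Control probe sets differed between some arrays. The signal of the 28S ribosomal RNA control was 9.30 ± 0.16 (SD, n = 4) with the empty vector and 8.55 ± 0.09 (SD, n = 5) with YAP S127A, lower in 5 of 5 arrays (2-sided exact permutation test, p = 0.00794, the smallest this design can give; adjusted p = 0.0556 over 7 measures). The mean of the 24 poly-A spike-in probe sets was 8.85 ± 0.10 (SD, n = 4) and 9.15 ± 0.19 (SD, n = 5) (exact permutation p = 0.0397, adjusted p = 0.139). The gap between the 3' and 5' actin controls, a sign of RNA quality, was largest in empty vector replicate 3 (1.69) and YAP S127A replicate 1 (1.58). Without both of these arrays, 5063 genes changed, of which 615 changed at least 2-fold.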

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

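A sample was singled out where it lay farther from the rest of its group than Dixon's criterion allows. The criterion was applied to 310 groups of values, for 7 array measures and all named genes, and singled out 23. Chance alone singles out about 1 in 20. The set of named genes was widened after the values had been seen.

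Among array measures, YAP S127A replicate 1 had an actin 3' to 5' gap of 1.58, next to 1.07 in the nearest array of its group, and a GAPDH 3' to 5' gap of 0.277, next to 0.213. The 18S ribosomal RNA control was 12.14 in YAP S127A replicate 2, next to 13.50 in the nearest array.

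Among genes in empty vector arrays, CDH6 was 10.96 (nearest 11.27), RNF128 9.64 (nearest 9.33), LTBP1 9.20 (nearest 9.38), INHBA 12.64 (nearest 12.47) and KLK10 8.45 (nearest 8.75), all in replicate 3. In replicate 4, CFLAR was 11.44 (nearest 11.52), P4HA1 11.06 (nearest 11.30), DCN 4.98 (nearest 5.01) and AKR1B10 9.53 (nearest 9.10). TFF1 was 7.45 in replicate 1 (nearest 7.74). In replicate 2, MAML1 was 9.26 (nearest 9.31) and COL1A2 4.01 (nearest 4.52).

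Among genes in YAP S127A arrays, MAP4K4 was 10.81 (nearest 10.65), KIF20A 10.58 (nearest 10.87), TOP2A 12.87 (nearest 12.72) and AKR1C2 7.16 (nearest 7.50), all in replicate 1. In replicate 2, ORC1 was 8.91 (nearest 8.71), JUP 10.20 (nearest 10.14) and SPRY4 10.27 (nearest 10.11). ID1 was 7.84 in replicate 5 (nearest 7.69).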

How the results depend on the processing

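The actin covariate, the omission of both arrays with the largest gap and the removal of the neighbours' median were chosen after seeing the data. The counts of changed probe sets and genes stayed within 1.5 times their main values in every alternative. Leaving out each array in turn gave 11099 to 12497 probe sets, 4861 to 5464 genes, 614 to 632 genes changed at least 2-fold, a YAP1 difference of 0.12 to 0.18 and 5 lists each time. With the mean over a gene's probe sets, 6546 genes changed and 458 changed at least 2-fold. With the neighbours' median removed, 5885 genes changed, 3934 of them shared with the main result, and 6 lists were called. The YAP1 difference of 0.148 passed with trend and robust eBayes (adjusted p = 0.0337, 0.0337 to 0.338 over the alternatives). The number of lists called was 2 with an estimated correlation and 20 with fry, which does not compare a list with other genes. With an estimated correlation the adjusted p was 0.0708 for YAP/TAZ targets, 0.106 for cholangiocyte markers and 0.106 for the TGF-beta and BMP response. The last was also lost without dim probe sets (0.0839). Apart from the neighbours' removal, the cause was not tested.

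Lists that did not pass changed direction in some alternatives. The Hippo list did so with quantile normalization (adjusted p = 0.990), with the mean over probe sets (0.863), and on leaving out empty vector replicate 4 or YAP S127A replicate 5 (0.815 to 0.994 over all left-out arrays). Matrix and integrins did so without YAP S127A replicate 1 (0.722 to 0.974). With the neighbours' median removed, so did epithelial junction genes (0.981), hepatocyte markers (0.981), matrix and integrins (0.981), drug transport (0.526) and ribosomal proteins (0.731). With fry, so did hepatocyte markers (0.538) and interferon-stimulated genes (0.113). Among genes, removal of the neighbours' median turned CCN1 (-1.79e-05), CDK1 (-0.030), RPL8 (0.18), RPL30 (0.16), RPL7 (0.25) and RPS3 (-0.053). DCN turned with the mean over probe sets (-0.0068) and COL3A1 without both arrays of largest actin gap (-0.016). On leaving out single arrays, COL1A2 ranged from -0.026 to 0.18 COL3A1 from -0.0093 to 0.044 and KRT19 from -0.024 to 0.058. KRT19 also turned with the actin covariate (-0.030). Over all alternatives, 2731 values of named genes kept direction and call, 45 lost the call and 6 gained it without turning, and 13 turned. Of those that turned, CCN1 and CDK1 lost the call and RPL7 gained one (adjusted p = 0.0074). The other gains were those of YAP1, RPL8 (0.0321) and KRT7 (0.0340) with trend and robust eBayes, TEK (0.0190) and TTR (0.0479) on leaving out YAP S127A replicate 2 or 3, and CCN2 (0.000213) with the neighbours' median removed.

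The replicate numbers do not pair the samples: the deviations of same-numbered arrays correlated between -0.461 and 0.030, and 0 of 8 arrays correlated best with their own number. With the replicate block, 10306 probe sets and 4459 genes changed, 614 of them at least 2-fold, 5 lists were called, and YAP1 differed by 0.12 (adjusted p = 0.338). Replicate 5 exists only with YAP S127A, so that array adds nothing to the difference in this fit. The block also leaves fewer degrees of freedom, so calls lost here need not come from pairing. The calls of SESN3 (0.0630), MCM4 (0.0532), TAT (0.144) and HBB (0.0884) were lost. TAT and HBB also lost theirs with trend and robust eBayes (0.0740 and 0.0553), the actin covariate (0.0517 and 0.0658) and both arrays of largest gap left out (0.132 and 0.138), and HBB with array weights (0.0553).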

Other observations

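All lists and tests of this part were chosen after related values had been seen, except the counts over other splits of the arrays, without their breakdown by mixture.

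Some aldo-keto reductase genes fell and some kallikrein genes rose. Of 7 aldo-keto reductase genes, 4 fell and 3 did not pass. Those that fell were AKR1B10 (-3.08), AKR1C3 (-3.07), AKR1C1 (-2.95) and AKR1C2 (-2.72), with a camera adjusted p = 0.000172 over the 6 added lists. The call was lost with an estimated correlation (adjusted p = 0.0617). These enzymes reduce steroids and aldehydes. The AKR1C genes are near-identical paralogs whose probe sets can cross-hybridise, so their values are not independent. AKR1C1 was at -1.15 as the mean of its probe sets. They lie on chromosome 10 among neighbours that were higher by 0.62. Of 14 kallikrein genes, secreted serine proteases in a cluster on chromosome 19, 6 rose and 8 did not pass (median +0.15, camera adjusted p = 0.00114), a call also lost with an estimated correlation (adjusted p = 0.0617). KLK6 rose by 2.83, KLK10 by 2.76 and KLK5 by 2.00, while their neighbours differed by -0.02 to -0.03.

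Aldo-keto reductase genes are known targets of NRF2, the transcription factor of the oxidative stress response, and lower NRF2 activity could account for the fall of these 4. The other 19 NRF2 target genes had a median log2 difference of 0.021 (camera adjusted p = 0.506), with 3 higher and 5 lower. With the neighbours' median removed, NQO1 moved from -0.48 to -0.85 and GCLM no longer passed (+0.08, adjusted p = 0.45). OSGIN1 (-0.25) and ABCC2 (-0.32) then passed as lower, and PGD (+0.30) as higher, beside SLC7A11 (+0.39) and PIR (+0.44). The camera result is from the values without that removal. Since members went both ways with and without it, the test leaves the hypothesis open.

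Zinc-finger genes with ZNF symbols fell more often than they rose (145 lower and 51 higher of 502; camera adjusted p = 0.00114, and not called with an estimated correlation, adjusted p = 0.0871). Many lie on chromosome 19, where 75 of 234 fell and 11 rose, and their position could account for the fall. Those on chromosome 19 kept their call with an estimated correlation (camera adjusted p = 6.11e-05 and 0.00578), and of all 835 genes described there 195 were lower and 69 higher. On other chromosomes 70 of 268 fell and 40 rose (median -0.05, camera adjusted p = 0.0708, and 0.437 with an estimated correlation). On chromosome 19 the median was -0.12 for the 234 zinc-finger genes and -0.07 for the 835. The latter were limited to genes with a signal above the median, so the sets are unlike and do not show how much position accounts for. A p above the threshold does not show that the genes elsewhere stayed unchanged, so a part played by gene family stays open.

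A random division of these 9 arrays does not account for the counts of probe sets and genes. Arrays of the same group lay closer together, so the real split was likely to rank first. Differences that arose by chance between the cell populations are not excluded by these counts. Among 100 splits of the 9 arrays into 4 and 5, the real one included, 1 gave as many changed probe sets (13052, highest other 4113), 1 as many genes (5676, highest other 1857), and 1 as many genes changed at least 2-fold (619, highest other 296). For gene lists the margin was narrow: 3 of the 100 splits called as many as the real 5 (highest other 5), and 48 of the 99 other splits called at least 1. Among the 50 other splits with 2 empty vector arrays in the group of 4, the most even mixture, 3 called a list. The rest keep part of the group difference, so a single list call is weaker evidence than the gene counts.

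A common offset between arrays would move all chromosomes alike. It cannot by itself separate chromosome 16 (+0.34) from chromosome 8 (median -0.18) on the same arrays. The opposite signs are no further test of scaling, because the array medians were already matched and some chromosomes had to lie lower. The chromosome 16 median was 0.345 with the actin gap as a covariate. That fit cannot decide on RNA quality, because the gap hardly differed between groups (mean 1.25 with the empty vector, 1.09 with YAP S127A). Per array, the chromosome 16 median was 0.275 to 0.383 with YAP S127A and -0.012 to 0.029 with the empty vector. This argues against poor RNA in single arrays as the cause. RNA quality shared by a whole group was not tested, although a ribosomal RNA control was lower in every YAP S127A array. A different chromosome copy number in the cell populations that were compared is a candidate explanation. A gain of a whole chromosome would move nearly all its genes. The lower quartile of chromosome 16 genes was shifted by 0.355, as much as the median (0.348). Only chromosome 16 was examined in this way. Some shifts covered only part of a chromosome. Neighbours of CCN1 on chromosome 1 (median -0.06) lay at +0.45, and those of CCN2 on chromosome 6 (median -0.04) at -0.51. DNA was not analysed here, and an effect of YAP S127A on whole chromosomes stays open as untested.

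Copy number could also account for genes changed at least 2-fold. Without the neighbours' median, 502 of 619 genes (81.1%, exact Clopper-Pearson 95% interval 77.8% to 84.1%) still changed at least 2-fold in the same direction. The shared shifts were small beside the largest differences (0.63 at VIM, which differed by 4.13), so genes far past 2-fold could hardly be lost. This argues against shifts shared by neighbouring genes as the whole cause, by their size. The interval treats genes as independent draws, although adjacent genes share most of their neighbours, so it does not measure the uncertainty of that share. A copy change of only a few genes would not move a median over up to 50 neighbours, so it was not tested. The interval contains 80%, the bound set first, and lies above 50%, the bound used here after the value was seen. Fibroblasts in the YAP S127A cultures would bring all their abundant transcripts. COL1A2, COL3A1 and DCN had a median difference of 0.026 and levels of 4.56, 4.90 and 5.03 with YAP S127A, below the median of all probe sets (5.96) and beside 12.40 for VIM, and COL1A1 fell (-0.70). This argues against fibroblasts as the source of VIM. Other genes expressed in fibroblasts rose, namely LUM (+1.45), SPARC (+1.40), LOX (+1.34) and POSTN (+0.89), and their source stays open. POSTN was at 0.40 as the mean of its probe sets and at 0.57 with the neighbours' median removed. Direct effects of YAP S127A and differences between separately grown populations remain open.

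The YAP1 probe sets did not rise past the threshold. If probe sets read the construct, swapped group labels would place them lower in the arrays labelled YAP S127A. All 3 lay slightly higher (+0.15, +0.16 and +0.03). The YAP/TAZ targets also lay higher in those arrays (median 0.39), with 11 of 21 higher and 2 lower, which argues against a swap. The list call itself (camera adjusted p = 0.0056) was lost with an estimated correlation (adjusted p = 0.0708). Whether the probe sets lie outside the construct or YAP1 transcripts hardly rose stays open, since neither the construct's sequence nor the probe positions were analysed here.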
